A study of Arabidopsis thaliana with 6 samples.

How the data were processed

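Small RNA from leaf total RNA of Arabidopsis thaliana was measured by sequencing in 6 libraries, in 3 groups of 2 replicates: HD adapters with TAP, standard Illumina adapters with TAP, and HD adapters with the TAP step omitted. Groups and replicate numbers were taken from the sample titles and characteristics. The same extraction text, which names the standard adapters, stands on all 6 samples, so the adapter of each sample was taken from its characteristics. The deposited files hold, per distinct read sequence, the count of reads with that sequence, a whole number with no scaling by the authors that the values show. The submitters' processing notes name TAIR10 without saying what it was used for. The read trimmer, the length limits and any filter used by the submitters are not given in the sources used here. Every sequence occurred in 1 line of its file, the HD files held lengths from 17 to 32 nt and the standard files from 17 to 40 nt, and no columns of other samples were present. Library sizes ran from 16703471 to 29002232 reads and from 2653280 to 4253571 distinct sequences.

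Distinct sequences were placed on the TAIR10.1 assembly, organelles included, with bwa 0.7.19 at exact matches, up to 5000 positions per sequence, which 10 sequences exceeded. Sequences of 18 to 30 nt with a match entered the tests, 12394601 to 23461789 reads per library. Each read was put in 1 class by priority: ribosomal RNA, tRNA, snRNA or snoRNA, miRNA precursor gene, trans-acting siRNA gene, other plastid, other mitochondrial, protein-coding sense, protein-coding antisense, other annotated, intergenic. Ribosomal RNA included 3600 nt downstream of each annotated 5.8S gene and 451 loci found with blastn 2.17.0 at 90% or more identity to 5S RNA over at least 110 nt. Gene counts summed sense reads whose matches lay in 1 of 38319 annotated genes only. CPM of sequences refer to matched reads of 18 to 30 nt, and CPM of genes to the sum of the gene table. Neither CPM includes the composition factor used in the tests, so a ratio of CPM and a fitted fold change differ by that factor.

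Differences were tested with limma 3.58.1 in R 4.3.3 on log2 CPM with voom precision weights and empirical Bayes moderation, 1 fit over all 6 libraries in 3 groups, and Benjamini-Hochberg adjustment per contrast at 0.05. The main change to the plan concerned the tool: edgeR had been planned and was not used, because the deposited cells join sequence and count in 1 text and were not accepted as plain counts. A second test foreseen with DESeq2 was not run for the same reason. TMM factors were computed with 30% and 5% trimmed, and features needed 10 reads at the median library size in 2 libraries and 15 reads in total. The sequence table held sequences with at least 10 reads over all libraries. Classes and lengths were tested as shares of the library, without voom weights, with a pseudocount of 0.5 CPM and no composition factor. For the classes the moderation gave a single spread pooled over all of them, so each log2 fold change has the same SE of 0.135. The 2 contrasts share the HD libraries with TAP, so their results are not independent and were not correlated. Gene lists were tested with camera at a correlation of 0.01 and again with an estimated one. Only members that passed the count filter were tested, so counts of members given below refer to these. For example, these were 131 of 625 nuclear tRNA genes, 112 of 287 snoRNA genes, 17 of 82 snRNA genes and 149 of 326 miRNA precursor genes. The share of transcript starts used 40818 annotated starts, and library diversity the distinct sequences expected among 10000000 drawn reads. For both, an exact two-sided permutation test was run, whose smallest p for 2 libraries against 2 is 0.333. Shares of single libraries carry 95% Wilson intervals, ratios with few reads Clopper-Pearson intervals, and a group without reads was set at a floor of 3 reads per library. RNAfold 2.7.2, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served the remaining steps.

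The contrasts, 85 mature sequences, 15 gene lists, the rule for named items and the first set of alternatives were fixed before the data were examined. The rule names, per contrast, up to 6 called listed mature sequences in each direction whose groups do not overlap, 5 called genes in each direction with a mean of at least 20 CPM and groups that do not overlap, the 3 members of each list with the most reads, and 3 called sequences in each direction with a mean of at least 20 CPM. Alternatives were median-of-ratios size factors, library totals, no filter, at least 50 reads in 2 libraries, the replicate number as a block, the 2 groups of a contrast alone, leaving out each library, lengths of 20 to 24 nt, single genome matches, summed 3′ ends, reads split over matches, TMM over classes, distinct sequences, genome matches only, other windows around transcript starts and an estimated set correlation. Trend fits on log2 CPM with offsets of 0.5 and 2, and lengths of 17 to 32 nt only, were added after the data were seen. Tested on simulated counts with 100 features changed 2-fold and 100 changed 4-fold, the gene test recovered 48% and 74% of them for the adapters and 36% and 80% for TAP, with 4 false calls each. The sequence test recovered 7% and 42%, and 10% and 37%, with 2 and 0 false calls. The simulated counts had a single dispersion per table and equal group means apart from these changes. In the real adapter contrast 72.5% of tested sequences were called, so these false calls do not measure error control in such a setting. Reads without a genome match and reads outside 18 to 30 nt were left out of the sequence and gene tests.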

Results

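Small RNA libraries were sequenced from leaves of Arabidopsis thaliana grown in long days. The 6 libraries fell into 3 groups of 2 replicates. The first group was made with high-definition (HD) adapters, whose ligating ends carry random bases, after treatment with tobacco acid pyrophosphatase (TAP). This enzyme removes the cap or extra phosphates from the 5′ end of RNA and leaves a single phosphate. The second group was made with the standard Illumina adapters after the same treatment. For the third group, made with HD adapters, the TAP step was left out. The HD libraries labelled TAP+ held 19049260 and 16703471 reads, the standard libraries 29002232 and 23483827 reads, and the HD libraries labelled TAP− 19705405 and 20720053 reads, in the order of their replicate numbers. Of the reads of 18 to 30 nt, 80.2% ± 0.092 (SD, n = 2) matched the TAIR10 genome exactly in the HD libraries labelled TAP+, 84.3% ± 0.739 in the standard libraries and 79.6% ± 0.075 in those labelled TAP−. The correlation of log2 normalised read counts between replicates, across 2615 genes that are not independent observations, was 0.976, 0.982 and 0.973 in these groups. Counts differed between replicates by more than sampling noise, with a chi-square per degree of freedom of 22.4, 23.2 and 18.7. The labels do not say whether the replicates came from separate plants, so the p-values measure only the spread between these samples. Intervals and detection floors cover counting error only, because reads copied by PCR are not independent molecules. Values are means ± SD of 2 libraries, abundances are reads scaled to library size (CPM), and log2 fold changes carry their SE.

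The comparison of HD with standard adapters asked how the choice of adapter changes the small RNAs that a library reports. Both groups were labelled TAP+, so a doubt about the HD labels that is given below applies here too. Mature miRNAs moved in both directions with the adapter. The strand opposite the guide of miR390, the miRNA that starts production of trans-acting siRNAs from TAS3, stood at 1376 ± 165 CPM with HD adapters and 12.7 ± 3.05 CPM with standard adapters (log2 6.60 ± 0.25, adjusted p 1.75e-06). miR167d, which targets auxin response factor mRNAs, stood at 9917 ± 2544 CPM against 156 ± 34.1 CPM (log2 5.82 ± 0.27, adjusted p 2.03e-06). In the other direction, miR157a, which targets SPL transcription factor mRNAs that promote the adult phase, fell from 27227 ± 4103 CPM with standard adapters to 2721 ± 52.6 CPM with HD adapters (log2 −3.48 ± 0.20, adjusted p 3.12e-06). miR166a, which targets the class III homeodomain leucine zipper mRNAs of leaf polarity, fell from 17344 ± 6767 CPM to 2191 ± 841 CPM (log2 −3.15 ± 0.34, adjusted p 3.20e-05).

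Of 85 listed mature sequences, 78 could be tested, and 55 of them differed between the adapters. Of these, 40 were higher and 15 lower with HD adapters. Adjusted over the list alone, the count was also 55. Among guides 30 of 63 were higher and 12 lower. Among passenger strands 8 of 12 were higher and 2 lower, and among trans-acting siRNAs 2 of 3 were higher and 1 lower. The median log2 fold change of the list was 0.71, with a range from −3.48 to 6.60. Also higher with HD adapters was miR171b, which targets SCARECROW-like mRNAs (839 ± 223 against 10.9 ± 2.35 CPM, log2 6.09 ± 0.32, adjusted p 2.46e-06). miR393a, which targets auxin receptor mRNAs, stood at 1771 ± 995 against 43.2 ± 4.73 CPM (log2 5.07 ± 0.39, adjusted p 7.52e-06). miR172e, which targets AP2-like mRNAs, stood at 6.71 ± 0.662 against 0.293 ± 0.189 CPM (log2 4.35 ± 0.51, adjusted p 5.64e-05). miR828, a trigger of trans-acting siRNAs from TAS4, had 112 reads with HD adapters and 2 with standard adapters (adjusted p 1.58e-05), a ratio of 88.9 after scaling to library size, with a 95% Clopper-Pearson counting interval from 24 to 743.3. Lower with HD adapters was also miR165a, a relative of miR166a (556 ± 223 against 4615 ± 1262 CPM, log2 −3.25 ± 0.31, adjusted p 1.77e-05). The same held for miR157d (168 ± 9.61 against 1401 ± 257 CPM, log2 −3.21 ± 0.23, adjusted p 5.71e-06). miR447a stood at 8.73 ± 1.74 against 79.8 ± 7.36 CPM (log2 −3.36 ± 0.27, adjusted p 8.33e-06) and miR861 at 0.181 ± 0.141 against 2.01 ± 0.911 CPM (log2 −3.46 ± 0.62, adjusted p 0.000772). Reads of miR171b, miR393a, miR447a and miR165a matched 2 genome positions each, those of miR157a 3, of miR157d 4 and of miR166a 7. The members of these families are therefore not separated. Without replicate 2 of the standard libraries 20 of the listed sequences were higher and 24 lower with HD adapters, and without their replicate 1 the counts were 26 and 21.

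**Figure D1:**
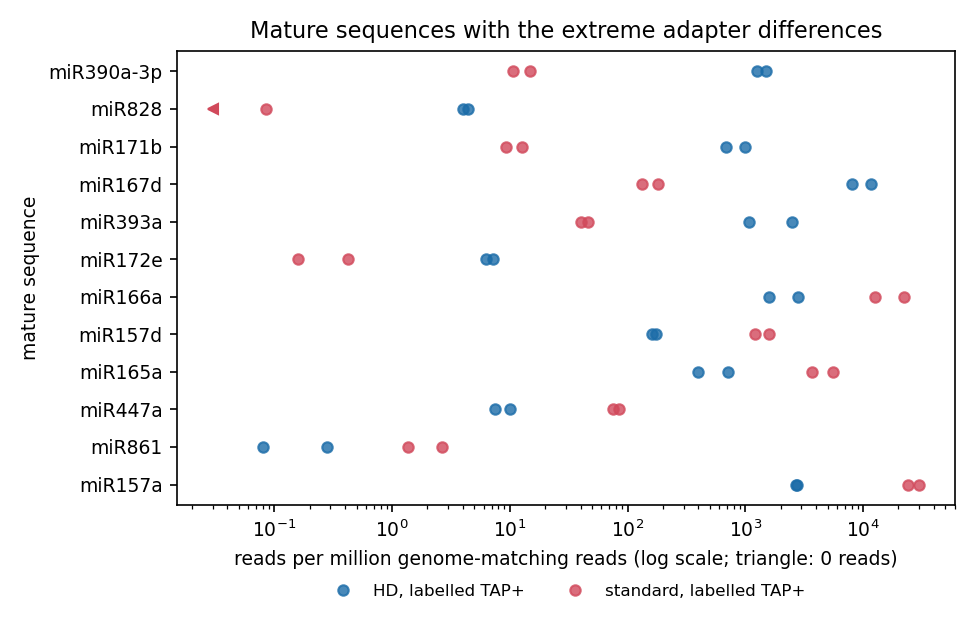
Abundance (CPM, log axis) of 12 listed mature sequences among genome-matching reads of 18 to 30 nt, 1 point per library, HD adapters against standard adapters with TAP. The sequences drawn were chosen among called ones whose HD and standard libraries do not overlap, and triangles mark libraries with 0 reads.

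The mature sequences lie in TAIR10 at chromosome 2, 16062023 to 16062043 (MIR390a, passenger strand), chromosome 1, 11137556 to 11137577 (MIR167d), and chromosome 4, 13847020 to 13847041 (MIR828). Further ones lie at chromosome 1, 3961367 to 3961387 (MIR171b), chromosome 2, 16652111 to 16652132 (MIR393a), and chromosome 5, 23988566 to 23988586 (MIR172e). Those lower with HD adapters lie at chromosome 1, 24921104 to 24921124 (MIR157b, whose sequence miR157a shares) and chromosome 2, 19176241 to 19176261 (MIR166a). The remaining ones lie at chromosome 1, 78932 to 78952 (MIR165a), chromosome 4, 1528190 to 1528211 (MIR447a), and chromosome 3, 17838154 to 17838174 (MIR861). All are in annotated miRNA precursor genes.

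Among called genes with a mean of at least 20 CPM and groups that do not overlap, counting reads that match 1 gene only, the largest rise with HD adapters was in the tRNA-His gene AT5G64735 (chromosome 5, 25875394 to 25875465), from 24.3 ± 8.70 to 5117 ± 2354 CPM of gene reads (log2 8.14 ± 0.31, adjusted p 3.38e-13). The precursor genes MIR167d (chromosome 1, 11137539 to 11137915) and MIR390a (chromosome 2, 16061954 to 16062060) rose from 1739 ± 337 to 85260.0 ± 21440.0 CPM (log2 6.04 ± 0.20, adjusted p 1.81e-14) and from 619 ± 92.2 to 17904 ± 915 CPM (log2 5.30 ± 0.16, adjusted p 1.15e-14). MIR828 rose from 0.721 ± 0.235 to 39.8 ± 2.17 CPM (log2 5.8 ± 0.81, adjusted p 1.95e-05). Reads that match MIR447a alone rose from 10 ± 0.865 to 419.6 ± 160.2 CPM (log2 5.74 ± 0.33, adjusted p 1.25e-10). The mature miR447a sequence, which matches 2 positions, is not in that count. Among the same genes the largest falls were in the small nucleolar RNA (snoRNA) gene AT1G75166 (chromosome 1, 28212518 to 28212603; log2 −3.80 ± 0.27, adjusted p 2.48e-09) and the snoRNA gene AT2G20722 (chromosome 2, 8931708 to 8931782; log2 −3.54 ± 0.32, adjusted p 9.89e-08). Next came MIR157d (log2 −3.49 ± 0.26, adjusted p 4.97e-09), the long noncoding RNA gene AT5G09505 (log2 −3.30 ± 0.27, adjusted p 1.69e-08) and AT2G20721, a snoRNA gene next to AT2G20722 (chromosome 2, 8931565 to 8931655; log2 −3.28 ± 0.27, adjusted p 2.16e-08). AT1G75166 stood at 14 ± 1.96 CPM with HD adapters and 269 ± 45.0 CPM with standard adapters.

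Among 149 tested miRNA precursor genes, 69 were higher with HD adapters, 18 were lower and 62 did not pass the test. The counts were 72 and 24 adjusted over the list alone, and the median log2 change was 0.54. MIR396a, whose miRNA targets growth-regulating factor mRNAs, did not pass (log2 0.17 ± 0.20, adjusted p 0.524), and MIR158a rose slightly (log2 0.68 ± 0.21, adjusted p 0.0179). Of 7 trans-acting siRNA loci, 5 were higher (5 higher and 1 lower adjusted over the list alone; median log2 1.21). TAS1A rose by log2 1.89 ± 0.19 (adjusted p 3.70e-07), TAS2 by 1.21 ± 0.16 (adjusted p 1.14e-05) and TAS1C by 0.75 ± 0.17 (adjusted p 0.00206). Among 13 genes of pentatricopeptide repeat proteins known as sources of secondary siRNAs, 3 were higher and 2 lower (5 and 2 adjusted over the list alone; median log2 0.20). AT1G63080 was higher (log2 1.11 ± 0.16, adjusted p 2.98e-05), and AT1G63130 and AT1G63150 fell short of the threshold (log2 0.16 ± 0.16 and −0.32 ± 0.15, adjusted p 0.445 and 0.101). AT1G63150 was called lower with library totals (log2 −0.77, adjusted p 0.000795), without a count filter (adjusted p 0.0430), with at least 50 reads in 2 libraries (adjusted p 0.0166) and at 20 to 24 nt (adjusted p 0.0113). NRPD1A, the largest subunit of RNA polymerase IV, which starts production of most 24 nt siRNAs, fell from 282 ± 37.4 to 31.2 ± 3.56 CPM (log2 −2.71 ± 0.20, adjusted p 5.06e-09). In the list of silencing genes 1 of 7 was higher and 1 lower, also adjusted over the list alone. AGO1 and DCL1, the main effector and the processing enzyme of miRNAs, did not pass (log2 0.23 ± 0.20 and 0.28 ± 0.26, adjusted p 0.392 and 0.418). That list's median was 0.23, its mean −0.24 and its set test pointed down. Among 15 miRNA target genes 2 were higher, also adjusted over the list alone (median log2 0.08). Of these the auxin receptor gene AFB2 was higher (log2 0.74 ± 0.16, adjusted p 0.00135) and AFB3 missed the threshold (log2 0.39 ± 0.15, adjusted p 0.0578). The calls of TAS1C and MIR158a ended without replicate 1 of the standard libraries (adjusted p 0.0757 and 0.333), without their replicate 2 that of AFB2 (adjusted p 0.0605) and without replicate 2 of the HD libraries that of MIR158a (adjusted p 0.176). Library totals as the scale also ended the calls of TAS1C, AFB2 and MIR158a (adjusted p 0.163, 0.151 and 0.377).

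Of 43 nuclear photosynthesis genes 30 fell (33 adjusted over the list alone; median log2 −0.76). As sets, this list and that of plastid photosystem genes did not pass with an estimated correlation (adjusted p 0.420 and 0.269). The genes that fell included CAB1 and LHCA1, which encode light-harvesting proteins (log2 −0.76 ± 0.16 and −0.72 ± 0.19, adjusted p 0.00159 and 0.00846), and RCA, rubisco activase (log2 −1.22 ± 0.21, adjusted p 0.000202). Of 13 plastid genes for photosystems and the large rubisco subunit 11 fell, also adjusted over the list alone (median log2 −0.87). These included psbN (log2 −0.65 ± 0.16, adjusted p 0.00500) and rbcL (log2 −1.06 ± 0.16, adjusted p 4.98e-05). In contrast psbA, the photosystem II reaction centre gene, did not pass (log2 0.06 ± 0.19, adjusted p 0.835) and was lower among reads of 20 to 24 nt alone (log2 −0.41). All 7 tested plastid genes read mainly by the nuclear-encoded polymerase fell, also adjusted over the list alone (median log2 −1.13). These included rpoA (log2 −1.48 ± 0.16, adjusted p 8.57e-07), clpP (log2 −1.13 ± 0.17, adjusted p 5.38e-05) and ycf1 (log2 −0.55 ± 0.18, adjusted p 0.0286). Among 6 stress genes 3 fell (1 higher and 3 lower adjusted over the list alone; median log2 −0.59). The cold-induced LTI78 and COR47 were among them (log2 −0.98 ± 0.20 and −1.06 ± 0.23, adjusted p 0.000882 and 0.00139), while KIN2 did not pass (log2 0.25 ± 0.22, adjusted p 0.388). The calls of CAB1, LHCA1, psbN, ycf1 and COR47 ended without replicate 1 of the HD libraries (adjusted p 0.0609, 0.0914, 0.113, 0.0989 and 0.0611). Those of LHCA1 and ycf1 also ended without replicate 2 of the HD libraries (adjusted p 0.0729 and 0.191) and without replicate 1 of the standard libraries (adjusted p 0.0558 and 0.0872).

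Of 112 tested snoRNA genes, which guide modification of ribosomal RNA, 13 were higher and 59 lower with HD adapters (14 and 65 adjusted over the list alone; median log2 −1.08). AT4G02555 fell (log2 −1.68 ± 0.16, adjusted p 2.44e-07), AT3G21805 did not pass (log2 0.33 ± 0.19, adjusted p 0.193) but was called higher without replicate 1 of the HD libraries (log2 0.68, adjusted p 0.0441). AT2G05765 fell over all lengths (log2 −1.80 ± 0.33, adjusted p 0.000360) but rose by log2 4.64 among reads of 20 to 24 nt. Of 17 spliceosomal small nuclear RNA (snRNA) genes 4 were higher and 6 lower (4 and 8 adjusted over the list alone; median log2 −0.27). U5.5 rose (log2 1.65 ± 0.18, adjusted p 1.09e-06), U2.5 fell (log2 −2.38 ± 0.19, adjusted p 1.80e-08) and U2.6 did not pass (log2 −0.27 ± 0.18, adjusted p 0.251), except with library totals (log2 −0.71, adjusted p 0.00430). Of 131 tested nuclear tRNA genes, from 625 in the list, 19 were higher and 12 lower, also adjusted over the list alone. The 3 most abundant all rose, AT1G63510 by log2 2.07 ± 0.18, AT5G41265 by 2.35 ± 0.19 and AT3G50665 by 1.33 ± 0.17 (adjusted p 7.08e-08, 1.34e-08 and 7.35e-06). The tRNA list's median was −0.03, or 0.15 with the 12 members that had no reads in a group set at their bound. Its mean was 0.03 and its set test pointed up. With library totals that set test passed (adjusted p 0.0267), while the median fell to −0.47. No call was made by limma among 5 ribosomal protein genes (RPL27AB, P40 and RPL34; median log2 −0.65) or among 5 histone genes (AT4G40040, AT4G40030 and HTA4; median log2 −0.46). There was 1 gene in each list at an unadjusted p under 0.05 and 0 adjusted over the list alone. Their log2 changes were −1.03 ± 0.53, −0.86 ± 0.36 and −0.18 ± 0.51 for the ribosomal protein genes (adjusted p 0.142, 0.0805 and 0.810). They were 0.42 ± 0.34, −0.93 ± 0.38 and −0.50 ± 0.37 for the histone genes (adjusted p 0.350, 0.0700 and 0.303). With library totals RPL27AB, P40, AT4G40030 and HTA4 were called lower (adjusted p 0.0329, 0.00967, 0.00825 and 0.0447), as was RPL27AB at 20 to 24 nt (adjusted p 0.0203) and with a trend fit (adjusted p 0.0476). None of 14 marker genes of flower, root and seed passed the count filter, so that list could not be tested.

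As sets compared with other genes at a preset correlation, the lists of nuclear photosynthesis (adjusted p 8.45e-11), plastid photosystem (4.31e-08), plastid genes of the nuclear-encoded polymerase (8.60e-06) and snoRNA genes (2.02e-09) were lower, and the miRNA precursors (3.50e-07) and trans-acting siRNA loci (0.000925) were higher. With a correlation estimated from the data no list passed, and these 6 had adjusted p of 0.420, 0.269, 0.269, 0.420, 0.246 and 0.269. At the preset correlation the pentatricopeptide repeat, silencing, miRNA target, stress, ribosomal protein, histone, snRNA and tRNA lists had adjusted p of 0.432, 0.628, 0.628, 0.212, 0.418, 0.503, 0.265 and 0.503.

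Over all sequences, the limma test called 97343 of 134343, 53722 higher and 43621 lower with HD adapters. Over genes it called 2181 of 7330, 1287 higher and 894 lower. Among sequences of miRNA precursor genes 869 were higher and 401 lower, among intergenic sequences 29061 and 18377, and among ribosomal RNA sequences 6226 and 10580. Higher calls made up 59.0% of the gene calls with TMM scaling and 21.3% with library totals as the scale. That scale moved the median log2 fold change of all genes from −0.05 to −0.49 and that of all sequences from 0.29 to 0.46. Sequence calls numbered 62585 without replicate 1 and 64215 without replicate 2 of the standard libraries. Gene calls numbered 1112 without replicate 1 and 1338 without replicate 2 of the HD libraries and 1437 without replicate 2 of the standard libraries.

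Single sequences were found with one adapter and were near or below detection with the other. The 3 named ones that were higher with HD adapters all contain GAATTC, bases at the start of the standard 3′ adapter. Loss of such reads in the standard libraries was not excluded. A 24 nt sequence opposite the noncoding RNA gene AT3G59765 (GACAAAAACAACACAGAGAATTCA, chromosome 3, 22076441 to 22076464) stood at 123 ± 19.4 CPM with HD adapters and had 0 reads with standard adapters, at least 771.9-fold higher at a floor of 3 reads per library. Its 23 nt form GACAAAAACAACACAGAGAATTC stood at 224 ± 55.8 CPM against 2 reads in all, a ratio of 4676.3 with a 95% counting interval from 1294.0 to 38622.6. The 29 nt fragment GGCTGTAGTTTAGTGGTAAGAATTCCACG of the tRNA gene AT1G02600 (chromosome 1, 552642 to 552670, 6 matches) rose from 0.250 ± 0.172 to 1015 ± 457 CPM (log2 11.80 ± 0.68, adjusted p 3.06e-06). With 0 reads under HD adapters, the 24 nt plastid sequence TTTTGATCTTCGAAACCAATTAAA, 163 nt upstream of psbD (32525 to 32548), stood at 683 ± 47.0 CPM with standard adapters, at least 2820.7-fold lower with HD adapters. The 18 nt intergenic sequence ACGGACATTGTTTAAACG has 2 genome matches, of which the first lies 360 nt upstream of IDH-IV (chromosome 1, 11740706 to 11740723). It also had 0 reads against 497 ± 380 CPM, at least 2054.8-fold lower. That limit was 3166.9-fold without replicate 1 and 943.5-fold without replicate 2 of the standard libraries. The 26 nt sequence TACCGATGATGATTATTGCTAAACTA of the snoRNA gene AT2G05765 (chromosome 2, 2184621 to 2184646) fell from 984 ± 240 to 0.323 ± 0.456 CPM (log2 −12.75 ± 0.86, adjusted p 4.57e-06).

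By annotation class, reads of snRNA and snoRNA genes made up 0.216% ± 0.00663 of genome-matching reads with HD adapters and 0.440% ± 0.0545 with standard adapters (log2 −1.03 ± 0.14, adjusted p 1.05e-07). Other plastid reads made up 5.42% ± 0.0496 and 8.49% ± 0.450 (log2 −0.65 ± 0.14, adjusted p 0.000178). Ribosomal RNA fell from 29.6% ± 1.94 to 22.2% ± 2.41 (adjusted p 0.0108) and mitochondrial reads also fell (log2 −0.48 ± 0.14, adjusted p 0.00434). tRNA rose from 8.43% ± 0.219 to 11.1% ± 0.294 (adjusted p 0.0121) and trans-acting siRNA loci from 0.816% ± 0.0122 to 1.07% ± 0.0509 (adjusted p 0.0121). Also higher were other annotated genes by log2 0.38 ± 0.14 (adjusted p 0.0121) and intergenic reads from 23.2% ± 0.155 to 29.5% ± 1.18 (adjusted p 0.0209). The test was not passed by miRNA precursor genes, at 12.2% ± 0.763 and 13.6% ± 0.767 (adjusted p 0.285), or by sense and antisense reads of protein-coding genes (adjusted p 0.499 and 0.0562). Of these 8 calls, 2 were left without replicate 1 of either group and 3 without replicate 2 of either group. Without the first HD, second HD, first standard and second standard library, the adjusted p of tRNA were 0.108, 0.0952, 0.0927 and 0.117, and of trans-acting siRNA loci 0.166, 0.0726, 0.0943 and 0.117. For the same libraries those of other annotated genes were 0.166, 0.0818, 0.0927 and 0.117, and of intergenic reads 0.176, 0.0904, 0.104 and 0.119. For ribosomal RNA they were 0.176, 0.0640 and 0.119 without the first HD, first standard and second standard library. For mitochondrial reads they were 0.0577, 0.0726 and 0.0927 without the first HD, second HD and first standard library. With TMM over the classes 2 calls were left, those of snRNA and snoRNA genes and of other plastid reads. At single genome matches the rises of intergenic reads, trans-acting siRNA loci and tRNA fell short (log2 0.013, 0.039 and 0.255, adjusted p 0.933, 0.888 and 0.19). There other annotated genes turned to log2 −0.046 (adjusted p 0.888) and miRNA precursor genes to a higher call (log2 0.447, adjusted p 0.0188). As distinct sequences tRNA turned to log2 −0.196 (adjusted p 0.226) and protein-coding sense reads to a lower call (log2 −0.424, adjusted p 0.00081), and ribosomal RNA and other annotated genes fell short (adjusted p 0.935 and 0.322). The SE of 0.135 was the same for every class, as the spread was pooled over the classes. The class p-values therefore do not measure the replicate spread of a single class. Because these are shares of a library, rises of some classes cannot be told apart from falls of others.

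**Figure D2:**
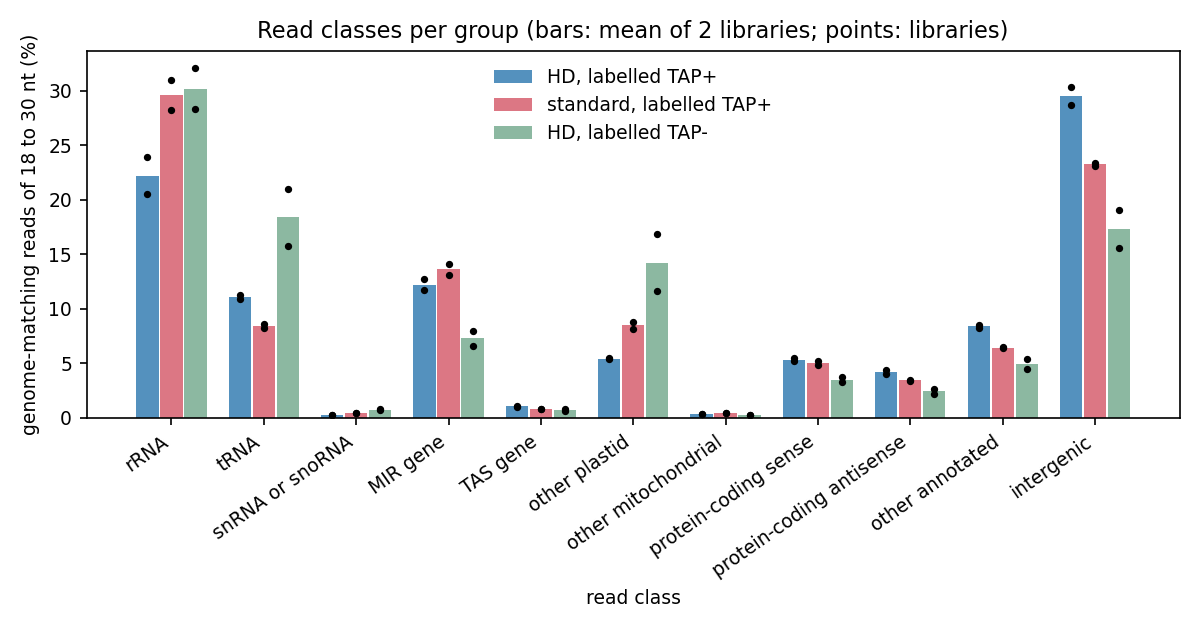
Share of genome-matching reads of 18 to 30 nt (percent) in 11 annotation classes, bars for the mean of 2 libraries and points for the libraries. Ribosomal RNA, tRNA and other plastid reads have larger shares in the HD libraries labelled TAP− than in those labelled TAP+, and intergenic reads have smaller ones.

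The siRNA length of 24 nt held 26.8% ± 1.22 of reads of 17 to 35 nt with HD adapters and 27.1% ± 0.938 with standard adapters (adjusted p 0.941). The miRNA length of 21 nt held 13.3% ± 0.0264 and 16.9% ± 0.830 (adjusted p 0.134). Longer reads were more frequent with HD adapters. They took 4.60% ± 0.155 against 1.22% ± 0.0203 at 30 nt (log2 1.92 ± 0.21, adjusted p 6.75e-08) and 4.95% ± 0.0574 against 1.62% ± 0.0524 at 31 nt (log2 1.61 ± 0.22, adjusted p 2.34e-06). Smaller rises were seen at 29 and 32 nt (log2 0.93 ± 0.21 and 1.23 ± 0.22, adjusted p 0.000754 and 7.45e-05). Reads of 18 nt fell (log2 −0.83 ± 0.26, adjusted p 0.00939). The HD files held no reads over 32 nt, so the 3 other calls, at 33 to 35 nt, compare files of unlike length range. Without replicate 1 of the standard libraries the calls at 18, 29, 31 and 32 nt ended (adjusted p 0.136, 0.124, 0.0953 and 0.136), as they did without their replicate 2 (adjusted p 0.492, 0.160, 0.0993 and 0.0993). Without replicate 1 of the HD libraries that at 18 nt ended (adjusted p 0.311), as it did over lengths of 17 to 32 nt alone (adjusted p 0.0505). As distinct sequences the call at 32 nt ended (log2 0.245, adjusted p 0.281), and 21 nt was called lower with HD adapters (log2 −0.23, adjusted p 0.0292).

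**Figure D3:**
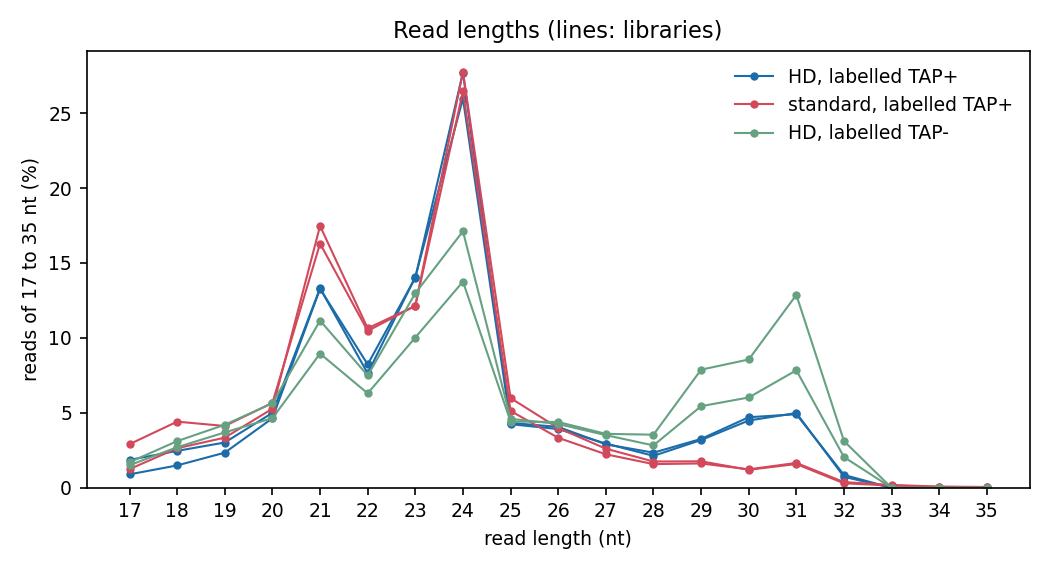
Share of reads of 17 to 35 nt (percent) at each length (nt), 1 line per library. All libraries peak at 24 nt, at lower shares in the HD libraries labelled TAP− (15.4% ± 2.38), and the HD libraries of both labels hold more reads of 30 and 31 nt than the standard libraries.

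At an equal depth of 10000000 reads of 18 to 30 nt, the HD libraries held 2278444 ± 50439 distinct sequences and the standard libraries 1908501 ± 36838 (SD, n = 2; exact two-sided permutation p 0.333, the smallest that 2 libraries against 2 allow). The 10 most abundant sequences took 10.2% ± 0.265 of the reads with HD adapters and 14.9% ± 0.390 with standard adapters (exact permutation p 0.333). Both differences were larger than the spread between replicates. The HD libraries labelled TAP− stood at 1830123 ± 122714 distinct sequences and 15.9% ± 1.60.

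The comparison of HD libraries labelled TAP+ with those labelled TAP− asked what opening capped and triphosphate ends to ligation adds to a library. Of 112 tested snoRNA genes 86 and of 131 tested nuclear tRNA genes 97 were lower in the libraries labelled TAP+. As sets, neither list passed with an estimated correlation (adjusted p 0.128 and 0.166). The snoRNA gene AT4G02555 (chromosome 4, 1122603 to 1122678) stood at 197 ± 20.8 CPM in the libraries labelled TAP+ and 7025 ± 364 CPM in those labelled TAP− (log2 −5.35 ± 0.17, adjusted p 9.02e-15). The plastid gene ndhH, of the NADH dehydrogenase-like complex (122011 to 123192), stood at 1112 ± 114 and 58761 ± 15229 CPM (log2 −5.90 ± 0.18, adjusted p 9.02e-15). The spliceosomal U2.6 snRNA fell from 1919 ± 251 CPM under the label TAP− to 366 ± 70.9 CPM under TAP+ (log2 −2.59 ± 0.18, adjusted p 1.94e-09). Of 78 tested mature sequences 1 passed the test, also adjusted over the list alone. This was miR161.2, which targets pentatricopeptide repeat mRNAs (chromosome 1, 17825722 to 17825742), at 66.1 ± 0.913 CPM under TAP+ and 177 ± 16.2 CPM under TAP− (log2 −1.84 ± 0.22, adjusted p 0.000515, and 0.000599 adjusted over the list alone). That call ended without replicate 1 of the libraries labelled TAP− (adjusted p 0.0683), while without replicate 2 of those labelled TAP+ there were 4 calls, 3 of them higher, and with library totals as the scale 8, of which 7 were higher.

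Also lower under TAP+ was AT3G01316, a snoRNA gene (chromosome 3, 104835 to 104909), from 1238 ± 347 to 40.3 ± 6.93 CPM (log2 −5.10 ± 0.24, adjusted p 1.08e-11). UBC9, a ubiquitin-conjugating enzyme gene (chromosome 4, 13915531 to 13917500), fell from 136 ± 9.89 to 4.77 ± 2.70 CPM (log2 −5.12 ± 0.42, adjusted p 3.53e-08). AT1G17090, a gene of an uncharacterized protein (chromosome 1, 5842168 to 5844367), fell from 109 ± 26.3 to 3.05 ± 0.538 CPM (log2 −5.17 ± 0.56, adjusted p 1.66e-06). Among called genes with a mean of at least 20 CPM and groups that do not overlap, the largest rise under TAP+ was in the transcribed pseudogene AT1G54985 (chromosome 1, 20509840 to 20511162), from 20.4 ± 1.35 to 58.6 ± 14.9 CPM (log2 1.30 ± 0.26, adjusted p 0.00191). It was followed by AT5G35604, annotated as a myosin heavy chain-like protein (log2 1.2 ± 0.33, adjusted p 0.0184), CYP71A14, a cytochrome P450 gene (log2 1.2 ± 0.34, adjusted p 0.0209), MIR405b (log2 1.15 ± 0.37, adjusted p 0.0478) and the long noncoding RNA gene AT2G08055 (log2 1.15 ± 0.25, adjusted p 0.00407). All 5 rises fell short of the threshold without replicate 1 of the libraries labelled TAP+ (adjusted p 0.0639, 0.251, 0.321, 0.519 and 0.152, in that order). Without replicate 1 of those labelled TAP− the same was true of CYP71A14, MIR405b and AT2G08055 (adjusted p 0.167, 0.0695 and 0.0753). Without their replicate 2 it was true of AT5G35604, CYP71A14 and MIR405b (adjusted p 0.293, 0.0604 and 0.382).

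Under the label TAP+ the count of snoRNA genes that fell was 86 of 112 (1 higher and 97 lower adjusted over the list alone; median log2 −2.35). AT3G21805 fell from 5614 ± 975 to 285 ± 89.0 CPM (log2 −4.52 ± 0.20, adjusted p 2.86e-12), while AT2G05765 did not pass (log2 0.72 ± 0.32, adjusted p 0.162). Without replicate 1 of the libraries labelled TAP+ its log2 change was −0.13 (adjusted p 0.827), and without their replicate 2 it was 1.57, a call (adjusted p 0.000625), as it was with library totals (adjusted p 0.0469) and without a count filter (adjusted p 0.000165). Of 17 snRNA genes 12 fell (13 adjusted over the list alone; median log2 −1.27). These included U2.5 (log2 −3.25 ± 0.19, adjusted p 2.54e-10) and U5.5 (log2 −2.48 ± 0.16, adjusted p 9.92e-10), the latter short of the threshold among reads of 20 to 24 nt alone (log2 −0.27, adjusted p 0.598). The count of nuclear tRNA genes that fell was 97 of 131 (104 adjusted over the list alone), with a median log2 of −3.26, or −2.75 with the 9 members that had no reads in a group set at their bound. The 3 tRNA genes with the most reads did not pass. AT1G63510, AT5G41265 and AT3G50665 had log2 changes of −0.29 ± 0.19, −0.18 ± 0.19 and −0.13 ± 0.17 (adjusted p 0.361, 0.586 and 0.674). Among 149 miRNA precursor genes 11 rose and 5 fell (5 and 1 adjusted over the list alone; median log2 0.18). MIR396a and MIR158a did not pass (log2 0.19 ± 0.20 and 0.08 ± 0.20, adjusted p 0.594 and 0.852) except without a count filter (adjusted p 7.80e-08 and 0.00421), and MIR167d rose (log2 0.64 ± 0.21, adjusted p 0.0451). The call of MIR167d ended without replicate 1 of the libraries labelled TAP+ (adjusted p 0.512) and without either library labelled TAP− (adjusted p 0.444 and 0.0771).

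Of 43 nuclear photosynthesis genes 16 fell under TAP+ (24 adjusted over the list alone; median log2 −0.63), but their 3 most abundant members did not pass. CAB1, LHCA1 and RCA had log2 changes of −0.49 ± 0.17, −0.10 ± 0.20 and −0.12 ± 0.23 (adjusted p 0.0611, 0.801 and 0.784). CAB1 was called lower without replicate 2 of the libraries labelled TAP− (adjusted p 0.0483), with at least 50 reads in 2 libraries (adjusted p 0.0331) and at 20 to 24 nt (adjusted p 0.0170). Among 13 plastid photosystem genes 1 fell, also adjusted over the list alone (median log2 −0.12). The genes psbA, psbN and rbcL did not pass (log2 −0.33 ± 0.19, −0.04 ± 0.16 and −0.14 ± 0.16, adjusted p 0.299, 0.894 and 0.618). Of 7 plastid genes read mainly by the nuclear-encoded polymerase 6 fell, also adjusted over the list alone (median log2 −1.06). These included ycf1 (log2 −1.56 ± 0.18, adjusted p 5.36e-06) and clpP (log2 −1.0 ± 0.18, adjusted p 0.000674), while rpoA did not pass (log2 −0.10 ± 0.16, adjusted p 0.749). Of 6 stress genes 3 fell (5 adjusted over the list alone; median log2 −0.96), among them KIN2 (log2 −1.5 ± 0.21, adjusted p 4.21e-05) but not LTI78 or COR47 (log2 −0.40 ± 0.22 and −0.66 ± 0.25, adjusted p 0.277 and 0.0948). COR47 was called lower without replicate 2 of the libraries labelled TAP− (adjusted p 0.0261). One of 5 ribosomal protein genes fell (2 adjusted over the list alone; median log2 −1.30). This was RPL27AB, which fell from 23.9 ± 0.676 to 3.05 ± 0.538 CPM (log2 −3.03 ± 0.51, adjusted p 0.000340). P40 and RPL34 did not pass (log2 −0.83 ± 0.41 and −0.91 ± 0.54, adjusted p 0.224 and 0.319). Of 5 histone genes 2 fell, also adjusted over the list alone (median log2 −0.64). Among them was the H3 gene AT4G40040 (log2 −1.28 ± 0.32, adjusted p 0.00983) but not HTA4 or AT4G40030 (log2 −0.61 ± 0.41 and 0.22 ± 0.54, adjusted p 0.389 and 0.838). The call of AT4G40040 ended without replicate 1 or 2 of the libraries labelled TAP+ (adjusted p 0.0507 and 0.132).

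No call was made by limma among the 7 trans-acting siRNA loci, the 13 pentatricopeptide repeat genes or the 15 miRNA targets, over all genes or adjusted over the list alone (0 in each). Each list had 2 members at an unadjusted p under 0.05, and the list medians were log2 0.32, 0.11 and −0.14. TAS1C, TAS2 and TAS1A had log2 changes of 0.13 ± 0.16, 0.09 ± 0.16 and 0.52 ± 0.19 (adjusted p 0.670, 0.779 and 0.0874). TAS1A was called higher without replicate 2 of the libraries labelled TAP+ (log2 0.87, adjusted p 0.0126), with median-of-ratios factors (adjusted p 0.0461) and with library totals (adjusted p 0.0184). Without a count filter all 3 were called higher (adjusted p 5.18e-05, 0.000192 and 2.78e-09). For AT1G63130, AT1G63080 and AT1G63150 they were 0.22 ± 0.16, −0.15 ± 0.16 and 0.09 ± 0.15 (adjusted p 0.437, 0.595 and 0.767). In the silencing list 1 of 7 genes fell, also adjusted over the list alone. NRPD1A, AGO1 and DCL1 did not pass (log2 0.43 ± 0.27, 0.22 ± 0.22 and 0.02 ± 0.29, adjusted p 0.344, 0.572 and 0.975). AFB2 and AFB3 had log2 changes of 0.36 ± 0.16 and 0.00 ± 0.16 (adjusted p 0.169 and 0.999), and AFB2 was called higher with library totals and without a count filter (adjusted p 0.0324 and 0.0114). The medians of the silencing and target lists were −0.07 and −0.14 and their means −0.27 and −0.16, whereas their set tests pointed up.

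In the set test at a preset correlation, snoRNA (adjusted p 9.39e-61), tRNA (2.31e-33), snRNA (3.03e-14), nuclear photosynthesis (2.68e-09), plastid genes of the nuclear-encoded polymerase (3.59e-06), stress (0.000978) and ribosomal protein genes (0.0256) were lower under TAP+, and the miRNA precursors (0.000677) and trans-acting siRNA loci (0.0400) were higher. With an estimated correlation no list passed, and the lowest adjusted p was 0.128, for the snoRNA and snRNA lists. At the preset correlation the plastid photosystem, pentatricopeptide repeat, silencing, miRNA target and histone lists had adjusted p of 0.282, 0.162, 0.885, 0.850 and 0.1. Without replicate 1 of the libraries labelled TAP+ the ribosomal protein and trans-acting siRNA lists had adjusted p of 0.0524 and 0.0621, and without replicate 1 of those labelled TAP− the latter had 0.350. Lower calls were gained by the plastid photosystem list without replicate 2 of the libraries labelled TAP+ (adjusted p 0.0395) and by the histone list without replicate 2 of those labelled TAP− (adjusted p 0.0192).

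Over all sequences, limma called 6804 of 134343, 615 higher and 6189 lower under TAP+. Over genes it called 966 of 7330, 83 higher and 883 lower. By class, 890 sequences of snRNA and snoRNA genes, 1727 of tRNA genes and 1056 other plastid sequences were lower. Of the sequences of miRNA precursor genes 10 were higher and 34 lower. Higher calls made up 8.59% of gene calls and 9.04% of sequence calls with TMM scaling, and 33.2% and 38.7% with library totals. That scale moved the median log2 fold change of genes from 0.00 to 0.19 and of sequences from 0.26 to 0.69. Sequence calls numbered 960 and 1782 without replicate 1 and 2 of the libraries labelled TAP−. Gene calls numbered 436 and 616 without these and 381 and 569 without replicate 1 and 2 of those labelled TAP+.

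Among called sequences with a mean of at least 20 CPM, the one with the largest rise under TAP+ was TCAACGAGAACAGAAATCT. It lay in AT3G06365 (chromosome 3, 14202770 to 14202788, 2 matches), which is annotated as a miscellaneous RNA gene, and was counted in the ribosomal RNA class. It stood at 330 ± 49.1 CPM against 20.7 ± 3.74 CPM (log2 3.57 ± 0.28, adjusted p 5.84e-05). Its shorter and longer forms CAACGAGAACAGAAATCT and CTCAACGAGAACAGAAATCT rose by log2 3.57 ± 0.32 and 2.70 ± 0.36 (adjusted p 0.000127 and 0.00121). Their calls ended without replicate 1 of the libraries labelled TAP− (adjusted p 0.0528 and 0.153), and the latter also without their replicate 2 (adjusted p 0.0958). Among the same sequences the 3 largest falls were in tRNA fragments. CTAGACTCTGAATCTAGTAACCCGAGTTCA, from the tRNA gene AT1G01270 (chromosome 1, 111906 to 111935), had 1 read under TAP+ and 1788 under TAP−, a ratio of 1731.2 with a 95% counting interval from 310.3 to 68414.9. CTGAATCTAGTAACCCGAGTTCA, from inside it, stood at 0.146 ± 0.0918 and 108 ± 8.34 CPM (log2 −9.72 ± 0.50, adjusted p 1.07e-05). AGTCCAACGGTTAGGATAATTGC, from the tRNA gene AT2G27850 (chromosome 2, 11864195 to 11864217, 12 matches), had 3 and 1643 reads, a ratio of 530.3 with an interval from 181.1 to 2573.9.

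By annotation class, snRNA and snoRNA reads took 0.216% ± 0.00663 of genome-matching reads under TAP+ and 0.733% ± 0.0403 under TAP− (log2 −1.77 ± 0.14, adjusted p 1.43e-13). The shares were 5.42% ± 0.0496 and 14.2% ± 3.70 for other plastid reads (log2 −1.37 ± 0.14, adjusted p 6.27e-11). For tRNA they were 11.1% ± 0.294 and 18.4% ± 3.71 (adjusted p 1.14e-05), and for ribosomal RNA 22.2% ± 2.41 and 30.2% ± 2.64 (adjusted p 0.00258). miRNA precursor genes rose from 7.28% ± 0.936 to 12.2% ± 0.763 (log2 0.75 ± 0.14, adjusted p 6.10e-06). Trans-acting siRNA loci rose from 0.699% ± 0.0976 to 1.07% ± 0.0509 (adjusted p 8.24e-05) and intergenic reads from 17.3% ± 2.44 to 29.5% ± 1.18 (log2 0.78 ± 0.14, adjusted p 5.19e-06). Sense and antisense reads of protein-coding genes and other annotated reads also rose (log2 0.62 ± 0.14, 0.78 ± 0.14 and 0.77 ± 0.14, adjusted p 8.26e-05, 5.19e-06 and 5.19e-06), and mitochondrial reads did not pass (adjusted p 0.0551). Here too the SE was pooled over the classes, so the p-values do not measure the replicate spread of a single class. Because these are shares of a library, the rises cannot be told apart from the falls of tRNA, ribosomal RNA and other plastid reads. On the scale of library totals the median log2 change of all sequences was itself 0.69. With TMM over the classes 6 classes were still called higher. Without replicate 1 or 2 of the libraries labelled TAP− mitochondrial reads were called higher (log2 0.294 and 0.242, adjusted p 0.00548 and 0.0189). The call of ribosomal RNA ended without replicate 1 of the libraries labelled TAP+ (adjusted p 0.107), with TMM over the classes (adjusted p 0.132) and as distinct sequences (adjusted p 0.0588), and at single genome matches its direction turned (log2 0.254, adjusted p 0.148). At single matches the rise of protein-coding sense reads also fell short (log2 0.21, adjusted p 0.218). As distinct sequences these reads and trans-acting siRNA loci turned to lower calls (log2 −0.231 and −0.179, adjusted p 0.00352 and 0.0474) and miRNA precursor genes to log2 −0.097 (adjusted p 0.0943). Antisense and intergenic reads then fell short (adjusted p 0.399 and 0.0828). Reads of 24 nt took 26.8% ± 1.22 under TAP+ and 15.4% ± 2.38 under TAP− (log2 0.81 ± 0.20, adjusted p 0.00300). Reads of 19, 29, 30, 31 and 32 nt fell (log2 −0.57 ± 0.21, −1.02 ± 0.21, −0.64 ± 0.21, −1.02 ± 0.22 and −1.67 ± 0.22, adjusted p 0.0414, 0.000935, 0.0220, 0.00118 and 6.82e-06). Without replicate 1 of the libraries labelled TAP+ 3 of these 6 length calls were left, as those at 19, 24 and 30 nt ended (adjusted p 0.552, 0.101 and 0.146). The call at 30 nt also ended without their replicate 2 (adjusted p 0.146), and that at 19 nt without any of the other 3 HD libraries (adjusted p 0.0618, 0.166 and 0.246). Over genome matches only the call at 30 nt ended (adjusted p 0.0668), and over lengths of 17 to 32 nt alone that at 19 nt (adjusted p 0.0521).

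Among sense reads of nuclear protein-coding genes, the share that began within 10 nt of an annotated transcript start, where capped ends lie, was 1.56% ± 0.037 in the libraries labelled TAP+ and 2.98% ± 0.228 in those labelled TAP− (SD, n = 2; exact two-sided permutation p 0.333, the smallest possible). The difference of −1.42 percentage points was larger than the spread between replicates. The difference was −0.699 points for a window of 2 nt, −2.30 for 25 nt, −2.29 for distinct sequences and −2.90 for single matches. The share under the label TAP− was 1.91 times that under TAP+. Scaled to matched reads the starts held 833 ± 48.2 and 1038 ± 22.9 CPM, a ratio of 1.25, so much of the higher share lies in a smaller number of these mRNA reads. The libraries held between 420636 and 1220694 such reads. The 95% Wilson intervals ran from 1.56% to 1.61% and 1.5% to 1.56% under TAP+ and from 3.09% to 3.19% and 2.78% to 2.86% under TAP−. The standard libraries, also labelled TAP+, stood at 1.12% ± 0.048.

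**Figure D4:**
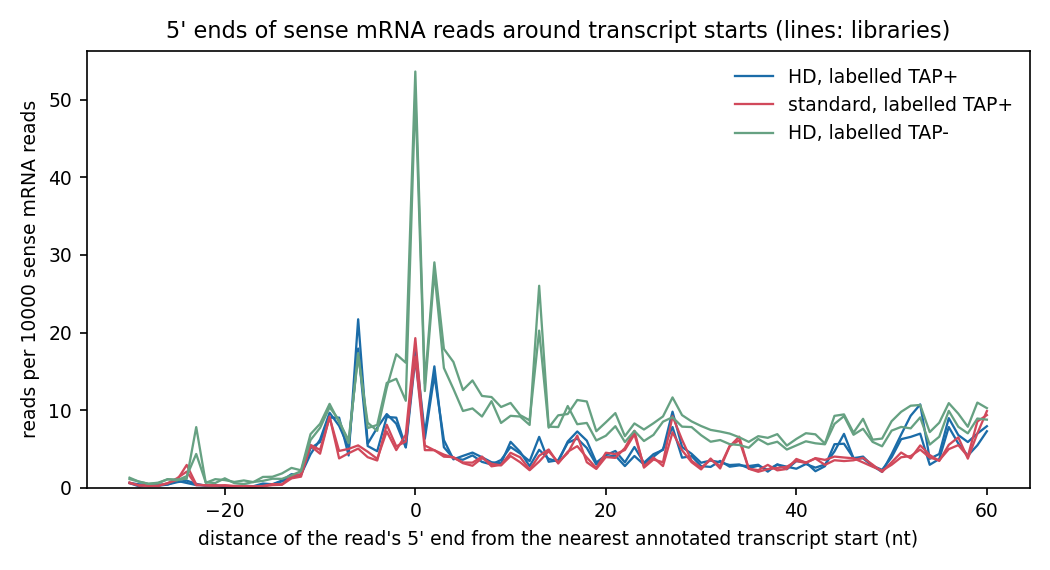
Reads with their 5′ end at each position from 30 nt before to 60 nt after annotated transcript starts among sense reads of protein-coding genes, scaled to equal numbers of these reads, 1 line per library. Both libraries labelled TAP− peak at the start itself, above all 4 libraries labelled TAP+.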

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

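The test of reads lacking 4 bases at the 3′ end was chosen after its result had been seen in part, and the test of inner GAATTC after these bases were noticed in the named sequences. The comparison of the standard libraries with either HD group was also chosen after its values were seen. The 2 items of unused reads that follow were also picked after their values were seen, from reads that entered no comparison. A 27 nt sequence without a genome match made up 5081.5 ± 1511 CPM of all reads in the HD libraries labelled TAP+ and 2693 ± 1194 CPM in those labelled TAP−, and had 0 reads in both standard libraries. Reads over 32 nt made up 0.394% of all reads in the standard libraries and none of the HD reads.

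The share of mRNA reads at transcript starts was higher under the label TAP−, although removal of caps should open such ends to ligation. A few genes with most of the start reads do not account for it, since without the 10 genes with the most the ratio of TAP− to TAP+ was still 1.99, and dilution by reads of siRNA length does not account for all of it, since at 25 to 30 nt it was 5.3. Dilution may still contribute, as the ratio was 1.4 at 20 to 24 nt and 1.25 for start reads scaled to matched reads. An exchange of the 2 HD labels is a candidate explanation, written down with its test beforehand: the capped U1, U2, U4 and U5 snRNAs also had more reads at their starts under TAP−, by a ratio of 3.62 (3.36% ± 0.392 against 0.93% ± 0.096). U6 snRNA, which lacks their trimethylguanosine cap, was also higher under TAP−, at 1.86% ± 0.479 against 1.0% ± 0.141. The rise at starts was thus not limited to RNAs with that cap. TAP also removes extra phosphates, so U6 is not a control untouched by TAP, and its value decides nothing about an exchange. At the starts of U1, U2, U4 and U5 the standard libraries labelled TAP+ stood at 0.20% ± 0.008, so an exchange of HD labels leaves their low share open. In 676 of 966 genes called in the TAP contrast the standard libraries stood nearer to the HD libraries labelled TAP+, and in 290 nearer to those labelled TAP−. Of 883 genes lower under TAP+, 654 stood nearer to TAP+ and 229 nearer to TAP−. Of 83 genes higher under TAP+, 22 stood nearer to TAP+ and 61 nearer to TAP−. In both directions most stood nearer to the HD group with the lower value, whichever its label. The counts therefore decide nothing about an exchange. Among the 654 was AT3G21805, at 301 ± 39.2 CPM with standard adapters, 285 ± 89.0 CPM under TAP+ and 5614 ± 975 CPM under TAP−. The adapter differs between these groups as well, so these counts do not exclude an exchange. The treatment itself is the difference that the design names. No test here sets its effect apart from an exchange of labels, so every TAP direction rests on the labels as given. The adapter contrast used the HD libraries labelled TAP+, so its directions rest on these labels as well. Under TAP−, snRNA and snoRNA reads (0.733%) lay above the standard libraries (0.440%) and intergenic reads (17.3%) below them (23.2%), the reverse of TAP+. Above the standard libraries under either label lay tRNA reads and miR167d, at 18.4% against 8.43% and 4507 against 156 CPM under TAP−.

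Some sequences were abundant with one adapter and near 0 reads with the other. Removal of 4 bases from the 3′ end of some HD reads may contribute: over 5000 abundant sequences the HD over standard ratio of reads exactly 4 nt short was at least 1.62 times the geometric mean of that for 3 and 5 nt short in each HD library labelled TAP+, where a plain mean had been foreseen, and 1.53 and 1.51 times in those labelled TAP−. Over 500 sequences of miRNA genes the lower quotient was 0.91, within the bound set against it. That quotient cannot decide there, because reads 5 nt short, which enter its divisor, had the higher ratios of 3.96 and 3.8. In the same HD libraries labelled TAP+, reads 4 nt short had ratios of 1.42 and 1.37, and reads 3 nt short 0.621 and 0.582. Loss of standard reads at inner matches to the start of the 3′ adapter stays open: the median log2 change of 2981 sequences with GAATTC exceeded that of 502 with CTTAAG by 0.32, between the bounds set for and against. The medians were 1.265 and 0.941, against 0.274 for 130868 sequences with neither. The 3 named sequences highest with HD adapters all contain GAATTC and were not among the 2981. No biological explanation was tested.

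Mature miRNAs differed in which adapter favoured them. Self-pairing of the mature sequence may play a part, since over 159 annotated sequences, which are not independent, the log2 change HD over standard had a Spearman rho of −0.2 with the folding free energy (Pearson r −0.264, permutation p 0.011, adjusted over 4 tests 0.044). With 1 sequence per family the rho was −0.201 over 83 sequences and missed the threshold (permutation p 0.071, adjusted 0.14). GC content stays open, with a rho of 0.12 (permutation p 0.14, adjusted 0.19), between the bounds set for and against, and 0.089 with 1 sequence per family (permutation p 0.42, adjusted 0.42), within the bound against. No biological explanation was tested.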

How the results depend on the processing

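Trend fits and the 17 to 32 nt limit were chosen after the data were seen. Of 2399 alternative values for single items, lists, classes and lengths, 2088 (87%) kept their direction and side of the threshold, 131 (5.5%) lost the call, 72 (3%) gained one, 97 (4%) had no call and moved or changed sign and 11 (0.5%) reversed. Part of the single items were named because their changes were the largest called ones in these data. At 33 to 35 nt no HD library held reads, so the TAP values there could not change. The 87% is therefore not a measure of how stable items picked without such a rule would be. With an estimated correlation 0 gene lists passed in either contrast. Without a filter, calls rose to 242311 sequences and 10884 sequences (adapter and TAP contrast) and 1937 genes (TAP), and with at least 50 reads in 2 libraries they numbered 25583 and 2644 sequences and 1290 and 245 genes, as other numbers of features were tested. Lengths of 20 to 24 nt gave 3412 sequences and 382 genes in the TAP contrast, and, at a depth of 8000000 reads in place of 10000000, a difference in diversity of 474193 sequences and −8.56 points in the top 10, where length and depth changed together. Single genome matches gave 52933 and 3336 sequences and 5 classes (adapters). TMM over the classes gave 2 classes (adapters). For listed miRNAs in the TAP contrast, library totals gave 8 calls (7 higher), summed 3′ ends 2, and each trend fit 2. Distinct sequences in place of reads gave 13 and 12 lengths and 6 classes (TAP). Lengths of 17 to 32 nt alone gave 4 (adapters). The difference in transcript start share was −0.699 points for a window of 2 nt, −2.30 for 25 nt, −2.29 for distinct sequences and −2.90 for single matches.

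These results reversed between adapters: psbA (log2 −0.41) and AT2G05765 (4.64) at 20 to 24 nt, the classes of miRNA genes (0.45) and other annotated genes (−0.046) at single matches, and tRNA (−0.20), protein-coding sense (−0.42) and 26 nt reads (−0.41) as distinct sequences. In the TAP contrast ribosomal RNA reversed at single matches (0.25), and miRNA genes (−0.10), trans-acting siRNA loci (−0.18) and protein-coding sense reads (−0.23) as distinct sequences. For these and the other moved values the cause was not tested.

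Leaving out 1 library at a time, where a lone library is assumed to vary like the other groups, adapter calls ran from 62585 to 71728 sequences, 1112 to 1461 genes, 44 to 53 listed miRNAs, 2 to 3 classes and 6 to 9 lengths, with 6 lists each time. TAP calls ran from 960 to 5780 sequences, 381 to 616 genes, 0 to 4 listed miRNAs, 7 to 10 lists, 9 to 11 classes and 3 to 9 lengths. The transcript start difference ran from −1.58 to −1.26 points and those of diversity from 334278 to 405610 sequences and −5.06 to −4.50 points. Replicate numbers recur across groups, but the labels do not say that they pair samples, and with 2 pairs a pairing cannot be settled: deviations of replicates correlated between groups across genes, which are not independent, at 0.358, 0.224 and 0.301, and across sequences at 0.543, 0.545 and 0.572. With the replicate block, calls were 101668 and 8694 sequences, 2639 and 1209 genes, and 12 listed miRNAs in the TAP contrast, 11 of them higher under TAP+. The DESeq2 alternative was not run. Depth limits items with few reads, and 2 libraries per group limit small changes.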

Other observations

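None of the values in this part was named in the plan. The first base of a small RNA guides its loading into an Argonaute protein, with U preferred by AGO1 and A by AGO4. Among 21 nt reads U came first in 64.7% ± 0.727 with standard adapters, 47.2% ± 1.79 in the HD libraries labelled TAP+ and 37.4% ± 1.0 in those labelled TAP− (SD, n = 2). C came first in 9.22% ± 0.900, 20.4% ± 3.05 and 19.4% ± 0.018. Among 22 nt reads A came first in 50.5% ± 1.58 with standard adapters and 35% ± 4.02 in the HD libraries labelled TAP+. Among 24 nt reads A came first in 55.0% ± 0.344, 58% ± 0.339 and 54.4% ± 0.979. No test was run on these shares.

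U6 snRNA, which carries no trimethylguanosine cap, began within 2 nt of its gene start in 1.86% ± 0.479 of reads under the label TAP−, 1.0% ± 0.141 in the HD libraries labelled TAP+ and 0.684% ± 0.148 in the standard libraries. Reads at mRNA starts, scaled to matched reads, stood at 1038 ± 22.9 CPM under TAP−, 833 ± 48.2 CPM under TAP+ and 559 ± 6.04 CPM with standard adapters. No test was run on these values either.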
